A study of Mus musculus with 4 samples.

How the data were processed

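Total RNA of single livers from 2 liver-specific Scap knockout mice and 2 wild-type littermates was labelled with Cy3 and hybridised to 4 arrays of 1 slide, read in 1 scan. Wild-type arrays lay at positions 1 and 2 and knockout arrays at positions 3 and 4, so position and group cannot be told apart. Spot intensity values were made with Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes; the processed intensity is background-subtracted and detrended within each array and not normalized between arrays, per the file headers. The deposited value tables hold log2 values; nothing in the sources used here states how the authors made them, and set against the scanner values they are log2 processed intensities after quantile normalization (r of 0.995 to 1.000 per array, each column median 4.69, not centred per gene). The 2 deposited tables of these values are identical. The authors' deposited table also gives a ratio, the fold of each knockout array over the wild-type mean. Probes over 100-fold in it number 2 for knockout 1 and 367 for knockout 2, of which 338 lie in the bright area described below, with a highest fold of 4038.

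Depth here is the share of spots well above background, given with the results; 0 spots were saturated. For the values reported, log2 of the processed intensity was taken minus each array's 75th percentile over non-control spots. Control spots and spots with an outlier mark were left out, and spots of 1 probe were averaged. A gene was tested if a probe was well above background on both arrays of at least 1 group and had a value in each group. An array on which all spots of the probe were left out counted as above background. The gene was represented by its brightest such probe. Of 41174 probes, 27479 were named through their transcript accession in the RefSeq table of assembly GRCm38.p6, 7461 through the symbol in the deposited table only (679 symbols updated by synonym), and 6234 have no symbol; accessions changed 2756 symbols. The array annotation is of build mm9, so no coordinates are given. The design had assumed gene names and a mean signal column in the scanner files; the names came from the tables above, and normexp (offset 50) used the median signal.

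Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjustment over 15889 genes, 13896 of them with a symbol, threshold 0.05). An exact permutation test of 2 against 2 cannot go under p = 0.333 and was not used. Gene lists (27, of which 4 main ones concern sterol and fatty acid synthesis, the SREBP pathway and hepatokines) were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over the 27 lists; fry tests whether members move 1 way on balance and does not compare them with other genes. For a gene not well above background in a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. The methods were tested on simulated data built on the 15795 genes with 4 values.

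Groups, tests, lists, alternatives and the naming rule were fixed before the data were examined. The rule named Scap, Gpnmb, Srebf1 and Srebf2, the 8 largest rises and falls above background on all arrays, the members of each list past the threshold with the largest changes (4 for main lists, 2 for others), and the 3 largest bounds in each direction. As no gene passed over all genes, the rule was applied at an adjusted p over the list alone for list members and at an unadjusted p, outside the bright area, for the others. A few genes that the rule names are not reported here. That step, the bright area settings and any further gene named were chosen after values were seen. The bright area holds spots of knockout 2 with over 10% of neighbours (within 8 rows and 4 columns) over 2 above the median of the other arrays on the log2 scale; the same rule marked 0 spots on the other 3 arrays. Alternatives were normexp, quantile and median scaling, other filters on dim probes, the mean of a gene's probes, trend and robust variance models, the replicate number as a block, each array left out, and the deposited tables as the source.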

Results

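Liver RNA was measured on one-colour microarrays in 8-week-old male mice fed chow. The 2 knockout mice lacked Scap in the liver, and the 2 wild-type mice were littermates. SCAP is the escort protein that brings the SREBP transcription factors from the endoplasmic reticulum to the Golgi, where they are activated for lipid synthesis. The series title names Gpnmb, a glycoprotein described there as secreted by the liver, so the question taken from it was which liver genes, Gpnmb among them, differ when Scap is lost. Each array carried 43379 spots of 41174 probes. The share of spots well above background was 63.9% and 49.3% in knockouts 1 and 2, and 59.5% and 61.0% in wild types 1 and 2. Only 2 arrays per group limit the precision of every value. All changes are log2 differences, knockout minus wild type, after each array was set relative to its own 75th percentile; the median over all 15889 tested genes was -0.15.

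The arrays differed in ways that the groups do not account for. On the array of knockout 2 an area of 7987 spots (18.4%) was brighter than on the other arrays, and 3054 of the tested genes had their spot there. The scanner software marked 549 outlier spots on that array against 71 to 94 on the others. Genes of the exocrine pancreas, the tissue that makes digestive enzymes, were far higher in knockout 2 and wild type 2 than in knockout 1 and wild type 1. Over the 8 pancreas genes of the list the median log2 difference was 10.94 between the knockouts and 9.003 between the wild types, also with the 2 genes not well above background in wild type 1 at their limits. As 1 mouse of each group carried this signal, the list's change between the groups was not called (median 0.76, camera adjusted p = 0.231).

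**Figure D1:**
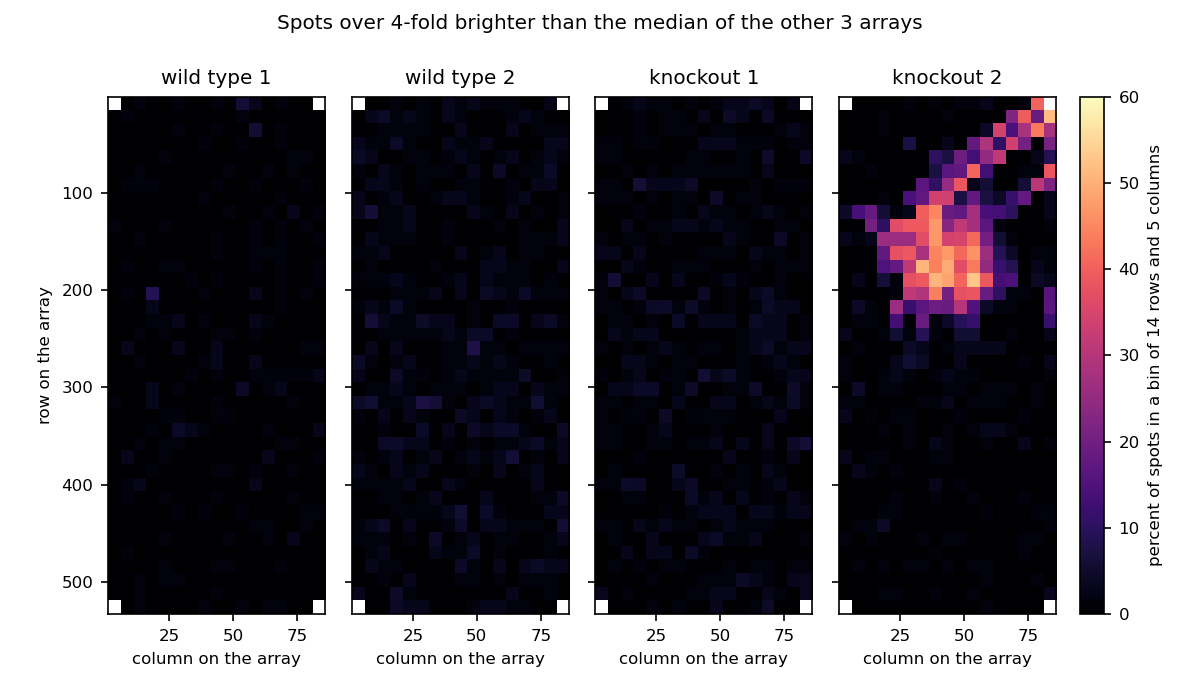
Percent of spots (colour) that were over 4-fold brighter than the median of the other 3 arrays, in bins of 14 rows and 5 columns, by row (vertical axis) and column (horizontal axis) on each array; white corners hold control spots only. The array of knockout 2 shows a bright area in its upper part, covering 7987 spots between rows 5 and 244 of 532, and the other 3 arrays show none.

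The targeted gene was lower in both knockout livers. Scap was measured by 1 probe at 3.52 ± 0.41 (SD, n = 2) in knockout and 5.59 ± 0.24 (SD, n = 2) in wild-type liver, a difference of -2.07 (SE 0.32), which limma gave an adjusted p of 0.295. The labels do not say which part of Scap was deleted, so a probe outside it would not check the genotype. Srebf1, the SREBP gene of fatty acid synthesis, differed by -3.28 (SE 0.47; limma adjusted p = 0.260), with its knockout 2 spot inside the bright area. Srebf2, the SREBP gene of cholesterol synthesis, differed by -1.06 (SE 0.26; limma adjusted p = 0.383), and 4 of its 4 probes had lower knockout than wild-type means.

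Gpnmb was not well above background in either wild-type liver and was detected in both knockouts. Its levels were 0.44 and -2.99 in knockouts 1 and 2 against -7.11 and -7.19 in wild types 1 and 2, at least 12.2-fold higher in knockout liver, with a measured difference of 5.87 (SE 1.13; limma adjusted p = 0.329). The level in knockout 1 was 3.42 above that in knockout 2 on the log2 scale, and the limit was 3.73-fold without knockout 1 and 40.1-fold without knockout 2. The authors' deposited table gives folds of 161.5 and 13.2 over the wild-type mean for knockouts 1 and 2, which rank 1 and 1192 among its 41267 probes. The ranks are not alike, as 338 of the 367 probes over 100-fold in knockout 2 lay in the bright area. The Gpnmb probe lay outside it. A second Gpnmb probe was not well above background on any array and has folds of 1.04 and 2.59 in the authors' deposited table. Normexp background correction brought the difference of the first probe to 1.48. Each array scaled to its median in place of its 75th percentile put both Gpnmb (5.72, limma adjusted p = 0.00168) and Scap (-2.22, limma adjusted p = 0.0328) past the threshold.

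Over all genes, limma called 0 at an adjusted p under 0.05 (smallest 0.222). At an unadjusted p under 0.05 there were 1699 genes, 373 higher and 1326 lower in knockout, where 794 are expected with no effect; 972 of them differed at least 2-fold. The groups did not overlap for 44.8% of genes, against 33.3% by chance. In data simulated for this comparison, limma recovered 0% of genes changed 2-fold or 4-fold, 68.5% of those changed 8-fold and 88% of those changed 16-fold. Median scaling gave 176 calls (66 higher, 110 lower), normexp gave 9 (0 higher, 9 lower), and the fit without knockout 1 gave 1308, of which 1110 were higher and 1041 of these had a spot in the bright area.

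**Figure D2:**
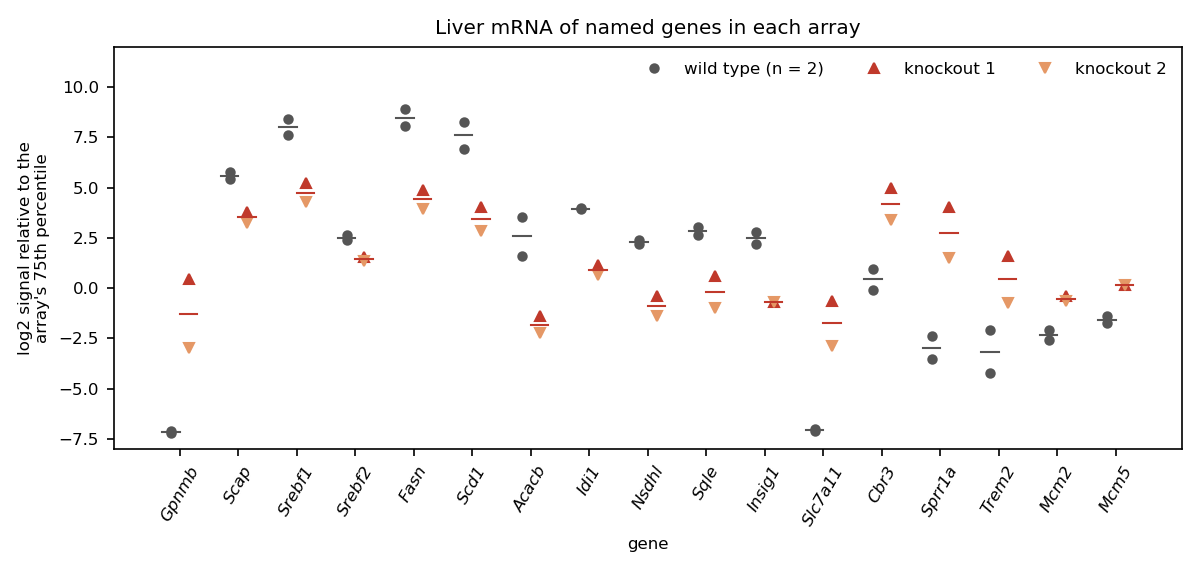
Liver mRNA of 17 named genes on each array (vertical axis, log2 signal relative to the array's 75th percentile; horizontal axis, genes); grey points are the 2 wild-type mice, triangles the 2 knockout mice, and short lines the group means. Fasn lies at 8.91 and 8.06 in wild types 1 and 2 and at 4.88 and 3.96 in knockouts 1 and 2, while Gpnmb is higher in both knockouts and differs between them.

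Genes of cholesterol synthesis fell together. Of the 20 genes measured, 17 fell adjusted over the list alone, 0 rose and 3 did not pass; 0 passed when adjusted over all genes. Idi1, which makes the isoprenoid building block dimethylallyl diphosphate, fell by 3.06 (SE 0.29), Nsdhl, a sterol dehydrogenase, fell by 3.16 (SE 0.40), and Sqle, the squalene epoxidase, fell by 3.04 (SE 0.58). Fdps, the farnesyl diphosphate synthase, fell by 3.44 (SE 0.43), with its knockout 2 spot in the bright area. Among the 3 others, Cyp51 and Lss had levels of 3.36 and 2.16 in knockout 2, where their spots lay in the bright area, and of -2.77 and -2.41 in knockout 1. The list's median was -1.90 and limma's camera placed it below other genes (adjusted p = 3.18e-16); with an estimated correlation the adjusted p = 0.423, and by fry the adjusted p = 0.0304.

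Most genes of fatty acid and triglyceride synthesis were also lower. Of 23 measured, 16 fell adjusted over the list alone, 1 passed upward and 6 did not pass. Fasn, the fatty acid synthase, fell by 4.07 (SE 0.47), Scd1, the main stearoyl-CoA desaturase of liver, fell by 4.17 (SE 0.63), and Acacb, an acetyl-CoA carboxylase, fell by 4.40 (SE 0.73). Fads1 and Thrsp, a desaturase and a regulator of lipogenesis, fell by 3.86 and 3.35. The 1 higher gene was Scd2, another desaturase (1.28, SE 0.33), but its spot in knockout 2 was marked as an outlier, so the wild types alone give its spread and knockout 1 is assumed to vary like them. The median was -1.86 and camera called the list (adjusted p = 2.70e-12), with an adjusted p = 0.546 with an estimated correlation and 0.139 by fry. Without wild type 1 the members that passed numbered 10 in place of 17.

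In the SREBP pathway and cholesterol uptake list, 8 of 13 measured genes fell adjusted over the list alone and 0 rose. Insig1, which retains SCAP in the endoplasmic reticulum, fell by 3.16 (SE 0.30), and Stard4, a sterol carrier with its knockout 2 spot in the bright area, fell by 2.29 (SE 0.25). Scap, Srebf1 and Srebf2 were among the 8, and Scap, the deleted gene, is no independent evidence of the list's direction. Insig2 had a difference of 0.01 and did not pass. The median was -1.51 with a camera adjusted p = 8.21e-09, an adjusted p = 0.423 with an estimated correlation, and 0.0651 by fry.

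The hepatokine list, of proteins that the liver secretes, had members past the threshold in both directions. Of 24 measured genes, 2 rose (Gpnmb and Tsku) and 2 fell, Angptl8 among them, adjusted over the list alone. Tsku rose by 1.75 (SE 0.37), and Angptl8, which takes part in restraining lipoprotein lipase, fell by 2.08 (SE 0.45). The series title itself names Gpnmb, so its place among the risers is not independent evidence. Fgf21 differed by 1.68 and Gdf15 by 0.21, and neither passed. The list was not called (median -0.28, mean -0.01, camera adjusted p = 0.504), and 0 of its genes passed when either wild-type mouse was left out.

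Among the remaining lipid and sugar lists, fatty acid oxidation and ketogenesis had 2 of 20 genes that fell adjusted over the list alone, Cyp4a10 (-3.37, SE 0.63) and Ehhadh (-1.79, SE 0.28), both of them targets of PPAR-alpha. Its median was -0.50 (camera adjusted p = 0.00340; adjusted p = 0.546 with an estimated correlation), and the camera call ended without knockout 1 (adjusted p = 0.0877) and with quantile scaling (0.108). In glucose metabolism and insulin signalling, 2 of 14 fell, the pyruvate kinase Pklr (-2.38, SE 0.27) and the glycogen synthase Gys2 (-1.54, SE 0.30), both with knockout 2 spots in the bright area (list median -0.69, camera adjusted p = 0.000275; adjusted p = 0.546 with an estimated correlation; 0.0644 without knockout 1). In phospholipid synthesis, Lpcat3 (-1.56, SE 0.26), with its knockout 2 spot in the bright area, and Pcyt2 (-1.28, SE 0.26) fell, 2 of 14. That list's median was -0.32 and its camera adjusted p = 0.0481 became 0.546 with an estimated correlation. It was 0.382 without knockout 1, 0.275 without wild type 1, 0.0595 without wild type 2 and 0.0779 without the bright area. Of 22 genes for lipoproteins, lipid uptake and lipid droplets, 0 passed by limma adjusted over the list alone (5 at an unadjusted p under 0.05), with a median of -0.48 (camera adjusted p = 0.0781), and Plin4, a lipid droplet coat protein, differed by 2.22. Of 17 bile acid and sterol export genes 0 passed by limma over the list alone, and 5 at an unadjusted p under 0.05 (median -0.76, camera adjusted p = 0.0133; adjusted p = 0.546 with an estimated correlation; 0.453 without knockout 1, 0.275 without wild type 1 and 0.124 with quantile scaling).

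Of 12 oxidative stress response genes measured, 6 rose adjusted over the list alone, 6 did not pass and 0 fell. Slc7a11, the cystine transporter, was not well above background in wild-type liver and was at least 8.78-fold higher in knockout liver (measured difference 5.32, SE 0.76), a limit of 4.04-fold without knockout 1 and 19.0-fold without knockout 2. The other Slc7a11 probes, each well above background on 1 array only, differed by 5.19, 1.93 and 5.30. Cbr3, a carbonyl reductase, rose by 3.76 (SE 0.65). Gsta1 and Gsta2, glutathione transferases, rose by 2.73 and 2.47. Nfe2l2, the transcription factor that drives many of these genes, differed by -0.70 and did not pass. The list median was 0.96 (camera adjusted p = 3.08e-09; adjusted p = 0.546 with an estimated correlation and 0.143 by fry).

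Of 13 cell cycle genes, 5 rose adjusted over the list alone and 0 fell. The largest difference on the list, 2.34, was that of Cdkn1a, an inhibitor of the cell cycle. Mcm2 and Mcm5, parts of the replicative helicase, rose by 1.81 (SE 0.30) and 1.73 (SE 0.27), whereas Mki67, a marker of cycling cells, differed by 0.55 and did not pass. The median was 0.84 (camera adjusted p = 3.08e-09; adjusted p = 0.546 with an estimated correlation and 0.143 by fry).

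**Figure D3:**
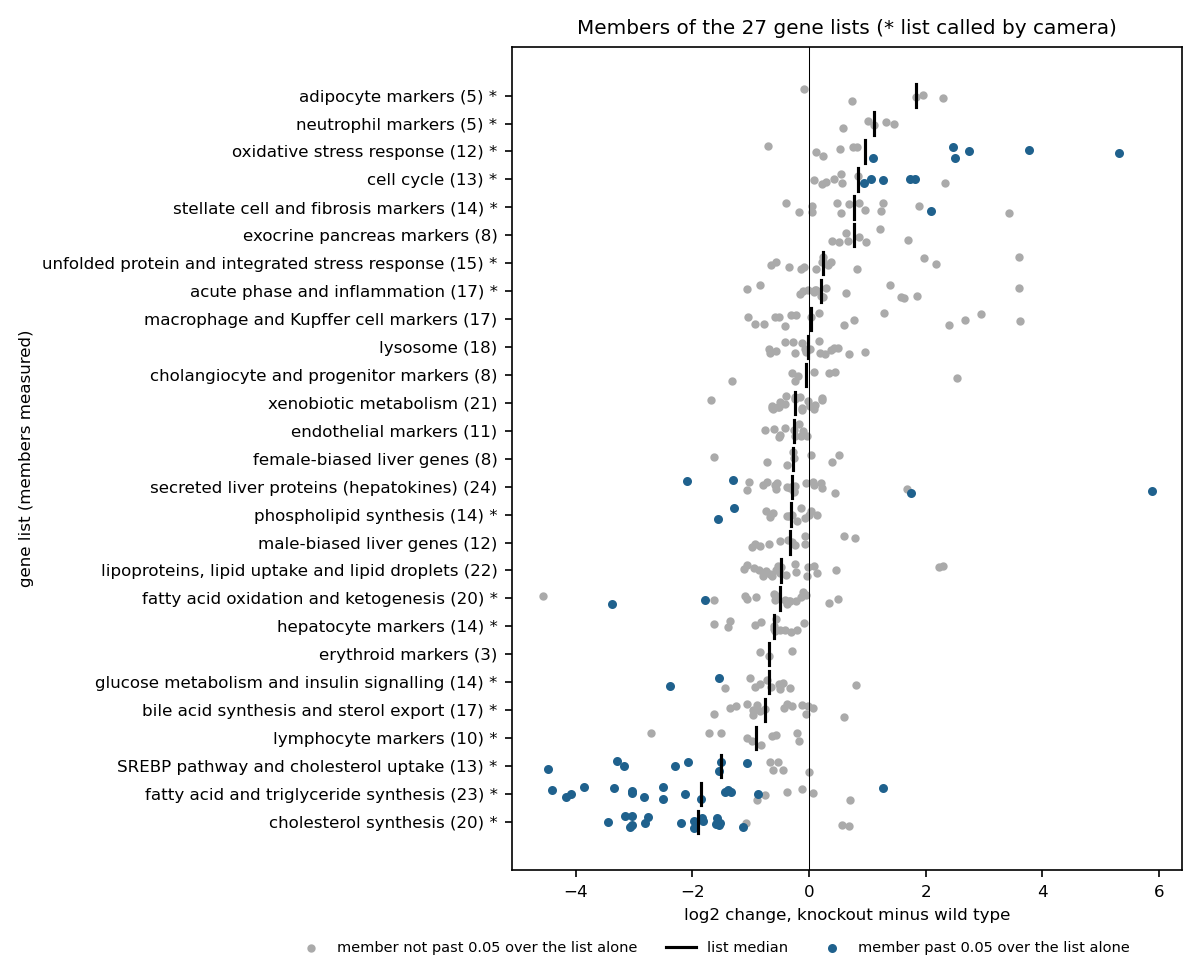
Log2 change, knockout minus wild type (horizontal axis), of each measured member of the 27 gene lists (vertical axis, with the number measured); blue points passed an adjusted p of 0.05 over their list alone, grey points did not, black bars are list medians, and asterisks mark lists called by camera. The medians run from -1.90 for cholesterol synthesis to 1.83 for adipocyte markers, a list of 5 measured genes.

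Camera placed some lists of cell type markers above other genes and some below, while 1 of their members passed adjusted over its list alone. This was the basement membrane collagen Col4a1 (2.10, SE 0.39), of 14 stellate cell and fibrosis genes, whose knockout 2 spot lay in the bright area. A second Col4a1 probe, outside that area, read 1.93 and 0.22 in knockouts 1 and 2 against 0.45 and 0.26 in the wild types, so knockout 2 was not higher by it. That list's median was 0.77 (camera adjusted p = 1.04e-05; adjusted p = 0.546 with an estimated correlation; 0.0803 without knockout 1). Camera also placed 5 neutrophil markers (median 1.12, adjusted p = 0.0392) and 5 adipocyte markers (median 1.83, adjusted p = 0.00683) above other genes, and 10 lymphocyte markers (median -0.90, adjusted p = 0.00677) and 14 hepatocyte markers (median -0.59, adjusted p = 0.000275) below them. With an estimated correlation their adjusted p = 0.609, 0.546, 0.546 and 0.546, and the adjusted p = 0.766 for neutrophils without knockout 1 and 0.393, with the direction turned downward, without wild type 1, 0.125 for adipocytes without wild type 1, 0.147 for lymphocytes without wild type 2 and 0.0877 for hepatocytes without knockout 1. By limma adjusted over the list alone 0 genes of these lists passed, while 0 neutrophil, 1 adipocyte, 4 lymphocyte and 4 hepatocyte markers had an unadjusted p under 0.05. The largest adipocyte difference, 2.29, was that of Cidec, which is also on the lipid droplet list. The 17 macrophage markers (median 0.04, camera adjusted p = 0.141), 11 endothelial markers (median -0.25, 0.200), 8 cholangiocyte and progenitor markers (median -0.05, 0.255) and 3 erythroid markers (median -0.68, 0.718) were not called.

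Camera called 16 of the 27 lists in all, 7 upward and 9 downward. Further calls were the acute phase and inflammation list (17 genes, median 0.20, adjusted p = 0.00683; 0.382 without knockout 1 and 0.283 without wild type 1) and the unfolded protein and integrated stress response list (15 genes, median 0.23, adjusted p = 0.0184; 0.682 without knockout 1). Their adjusted p = 0.584 and 0.546 with an estimated correlation. Lists not called were xenobiotic metabolism (21 genes, median -0.23, adjusted p = 0.446), male-biased liver genes (12 genes, median -0.33, 0.446), female-biased liver genes (8 genes, median -0.27, 0.718) and lysosome (18 genes, median -0.02, 0.326, with camera's direction upward). With an estimated correlation 0 of the 27 lists passed and 2 had an unadjusted p under 0.05. In simulated data for this comparison camera with its preset correlation found 50 of 50 lists of 20 genes shifted by -1.5. It made 2 false calls in 1300. Camera with an estimated correlation found 0 of 50, so a list that it did not call may still be shifted. Fry found 31 of 50. Smaller shifts and lists, as most of those called here have, were not simulated. Genes were simulated as independent, so the false calls cannot speak for lists whose members move together. Among the lists called here the estimated correlation ran from 0.03 (SREBP pathway) to 0.87 (neutrophil markers). By fry 1 of the 27 lists passed, cholesterol synthesis, and the adjusted p ranged from 0.0651 to 0.770 over the other 15 that camera called.

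Over all genes, those with the largest differences at an unadjusted p under 0.05, outside the bright area and above background on all 4 arrays, did not pass the adjustment over all genes. Higher values stood in knockout liver for Sprr1a, a cornified envelope protein (5.72, SE 0.93; limma adjusted p = 0.298), Elovl7 (4.22, SE 1.10), Nupr1, a stress-induced chromatin protein (4.13, SE 1.41), Cbr3 (3.76, SE 0.65), Trem2, a receptor of lipid-associated macrophages (3.61, SE 1.05), Lcn2 (3.59, SE 1.249), Cox6a2 (3.53, SE 0.80) and Ly6d (3.48, SE 0.52). Lower values stood for Cyp4a14 (-4.56, SE 1.23), Acacb (-4.40), Scd1 (-4.17), Fasn (-4.07), Fads1 (-3.86, SE 0.33), Hamp2 (-3.41, SE 0.28), Cyp4a10 (-3.37) and Thrsp (-3.35, SE 0.43). Without knockout 1, the differences were -2.72 for Cyp4a14, 2.53 for Nupr1 and 2.34 for Cox6a2. Without wild type 1 they were 2.67 for Nupr1 and 1.86 for Lcn2. Of genes not well above background in one group, Vmn2r3 and Mirg were at least 14.8-fold and 10.65-fold higher in knockout (limma adjusted p = 0.222 and 0.260), and Ppp1r3g, Fam83e and Slc26a3 at least 12.2-fold, 7.80-fold and 7.40-fold lower (limma adjusted p = 0.302, 0.394 and 0.453). The Mirg limit was 19.9-fold without knockout 1 and 5.70-fold without knockout 2. Those of Ppp1r3g, Fam83e and Slc26a3 were 7.98-fold, 2.93-fold and 1.37-fold without wild type 2, and 18.8-fold, 20.8-fold and 39.8-fold without wild type 1. They were 6.13-fold, 3.92-fold and 3.70-fold without knockout 1, and 24.5-fold, 15.5-fold and 14.8-fold without knockout 2. Wild type 2 carried the exocrine pancreas signal, but so did knockout 2, where these genes were not well above background.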

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

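Tests chosen after the result was seen were those on dim probes and on negative control spots for the bright area, and, for the pancreas genes, that on the wild-type arrays and the reading of islet genes within 1 group, and, for genes higher in knockout 1, the bright area acting through the scaling; bounds for the other tests were set beforehand.

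On the array of knockout 2, 12 of 153 negative control spots, which match no mouse transcript, were well above background, against 1, 1 and 2 on the other arrays (at positions of the same area), a signal outside the spots used for the comparison. These spots belong to the bright area, which holds 1629 of the 1830 spots over 8-fold above the median of the others on this array. Higher expression in that liver is argued against by the controls, since 12 of the 28 inside the area and 0 of the 125 outside it were above background (Fisher's exact test, two-sided p = 1.38e-10). The tests set beforehand did not decide: over 216 probes printed both inside and outside the area, the inside spots were brighter by a median of 0.29 on the log2 scale, under the bound of 1, and were brighter for 69.0% of probes, between the bounds set. Over the 104 dim probes among these the difference was 1.34 on this array and -0.07 to 0.03 on the others, so a stain that adds light mainly to dim spots is a candidate explanation, found and tested on the same data.

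Exocrine pancreas genes were far higher in knockout 2 and wild type 2 than in the other mouse of their group. The bright area is argued against, as the median difference between the wild-type arrays, which have none, was 9.003 over the 8 listed genes. Of 17 other acinar genes measured, 100% were over 2 higher on the log2 scale in both groups, which pancreas tissue taken along with the liver may produce; the median differences were at least 10.25 between knockouts and 7.52 between wild types, with the 8 genes not well above background in a first mouse at their limits. Of the islet hormone genes Ins1, Ins2 and Gcg, 0 of 3 passed this limit in both groups, but Ins2 was at least 17.7-fold higher in knockout 2 than in knockout 1, where it was not well above background. As Ins2 was not above it in either wild type and Ins1 on no array, pancreas tissue and an acinar programme of liver cells without islets cannot be told apart here.

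Gpnmb and other genes higher in knockout liver were higher in knockout 1 than in knockout 2. For 155 such genes at an unadjusted p under 0.05, at least 2-fold and outside the bright area, the median difference between the knockouts was 0.88, and 82.6% were higher in knockout 1. An offset that depends on intensity is argued against, since level-matched genes gave a median of 0.27 with a highest value of 0.46 in 10000 draws. Spots in the bright area are higher in knockout 2, and through the array's scaling the area would shift all genes outside it alike, which is argued against by the 0.88 of the 155 genes against a median of 0.26 over all genes outside it. For the 571 genes lower in knockout liver by the same limits the median difference between the knockouts was -0.07, with 46.9% higher in knockout 1; no biological explanation was tested, nor pancreas RNA in the second mouse.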

How the results depend on the processing

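Settings that leave out the bright area were chosen after the data were seen. The calls over all genes (0) became 9 with normexp (0 higher, 9 lower), 176 with median scaling (66 and 110), 300 with median scaling and no bright area (101 and 199), and 0 to 1308 with single arrays left out (higher 0 to 1110, lower 0 to 198); the other settings gave 0. Median scaling moved the median of all genes from -0.15 to -0.30 and limma's prior degrees of freedom from 2.79 to 14.2; with median scaling and no bright area these were infinite, so the 300 calls rest on 1 variance shared by all genes. What else added calls was not tested. Lower among the 300 were the acinar genes Sycn (-5.08), Amy2a5 (-3.06) and Cela1 (-3.00), whose knockout 2 spots lay in the bright area. Leaving the area out set knockout 1 alone against both wild types for these genes. Wild type 2 carried the pancreas signal, so these calls cannot be read as an effect of the knockout. Falls of genes outside the acinar set also leaned on wild type 2. Slc26a3 (-4.54) had main-fit levels of -3.97 and 0.88 in wild types 1 and 2, and Fam83e (-3.75) had -2.88 and -0.05. Their knockout 2 spots lay outside the bright area. How many of the 300 calls rest on 1 mouse was not tested. Genes at an unadjusted p under 0.05 numbered 1699, and 3511, 2705, 805 and 790 without knockout 1, knockout 2, wild type 1 and wild type 2; fewer samples enter each, and a lone mouse is assumed to vary like the other group. The other 2 splits of the 4 arrays gave 229 and 539.

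Among fits of all 4 arrays, Scap passed the threshold with median scaling (-2.22, also without the bright area), and Gpnmb passed likewise (5.72). With single arrays left out, Scap ranged from -2.36 to -1.78. The measured difference of Gpnmb, against wild-type signals not well above background, then ranged from 4.16 to 7.58. Its limits ranged from at least 3.73-fold to at least 40.1-fold. The cause was not tested. Cholesterol synthesis lost its call by camera with an estimated correlation (adjusted p = 0.423). The SREBP pathway lost its call by that test (0.423) and by fry (0.0651), and fatty acid synthesis likewise (0.546 and 0.139). Camera with an estimated correlation found 0 of 50 simulated shifted lists, so calls lost by it do not decide. All 3 lists kept the call and direction in every other setting. Members of the fatty acid list that passed ranged from 10 to 19 with arrays left out. Hepatokine members that passed (4) were 0 with normexp, quantile scaling, no filter, the mean of probes, each deposited table and the replicate block, 2 with median scaling and no bright area, and 0 to 2 with arrays left out.

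The hepatokine list was called without a filter (adjusted p = 0.0385) and turned upward, uncalled, with normexp (0.852), quantile scaling (0.517), both deposited tables (0.544) and median scaling without the bright area (0.481). Camera's direction also turned for neutrophil markers, a called list, without wild type 1 (0.393), and for lists not called. With normexp the adjusted p = 0.256 for xenobiotic, 0.852 for male-biased and 0.913 for female-biased genes; with quantile scaling 0.374, 0.759 and 0.726; with the deposited values 0.394, 0.813 and 0.807. It turned for female-biased genes with the mean of probes (0.420) and without the bright area on all arrays (0.966), for lysosome by fry (0.9498) and without a filter (0.769), and for erythroid markers without the bright area (0.456; 0.504 with a trend; 0.941 with median scaling). With arrays left out, directions turned within adjusted p ranges of 0.172 to 0.766 (lysosome), 0.00406 to 0.753 (xenobiotic), 0.00228 to 0.841 (male-biased), 0.0284 to 0.732 (female-biased), 0.0133 to 0.766 (cholangiocyte), 0.114 to 0.742 (erythroid), 0.000281 to 0.295 (pancreas) and 2.57e-05 to 0.766 (neutrophil). The cause was not tested. Of the alternatives for the other lists that kept the direction, 71 ended a call and 19 made one. For other named genes 705 kept their side of the threshold and direction, and 99 now passed it.

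Same-numbered mice are different animals, although the second of each group share the pancreas signal. Their deviations correlated at 0.168 over genes, and the replicate block left 0 calls over all genes and 1459 at an unadjusted p under 0.05. Signal over background limits dim genes: with 12868 genes above it on all 4 arrays (missing values again counted as above) limma called 0, at a smallest adjusted p of 0.142. Gpnmb is not among these genes.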

Other observations

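The macrophage markers below were grouped only after their values were seen. Clec4f (-1.04), Timd4 (-0.93), Vsig4 (-0.78) and Cd5l (-0.31), markers of resident Kupffer cells, were lower in both knockout livers than in both wild-type livers, and Marco, another, differed by 0.77. Trem2 (3.61), Cd14 (2.95), Ccr2 (2.67), Itgax (2.39) and Cd68 (1.29) are found on recruited or activated macrophages. The other 7 markers differed by -0.58 (Adgre1) to 0.61 (Lyz2), and the median of all 17 was 0.04. The knockout 2 spots of Clec4f, Cd5l and Ccr2 lay in the bright area. By limma, 0 of the 17 markers passed adjusted over the list alone, and 7 had an unadjusted p under 0.05. Spp1, osteopontin, with 1 in 5 of its knockout 2 spots in the bright area, differed by 2.54 and Timp1, an inhibitor of matrix proteases, by 3.43; neither passed over its list.

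Among B cell markers, Ms4a1 (-1.72), Cd79a (-0.98) and Cd79b (-1.06) were lower in both knockout livers than in both wild-type livers, and none passed by limma over its list of 10. Of the stress genes, Asns, the asparagine synthetase, had values of 5.54 and 5.28 in the knockouts and 0.50 and 3.10 in the wild types; its knockout 2 spot lay in the bright area.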
